A study of Mus musculus with 27 samples.

How the data were processed

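Whole hearts of 7 E13.5 embryos and ventricular apexes of 20 adult C57BL/6J mice (6 at 6 weeks, 6 at 16 weeks, 4 sham-operated and 4 under TAC) were sequenced from oligo(dT)-selected RNA as non-stranded single-end reads, per the labels. The files hold raw counts per feature, which the authors made with Bowtie, TopHat 1.3.0 and HTSeq on the mouse build mm9 (NCBIM37), per the submitters' processing notes, which also name DESeq and edgeR without saying what each did. The counting mode, its strand setting and any filter are not given in the sources used here. In each of the 27 files the summed counts equalled the total line, and the series table held the same values. The total line was left out of library sizes and tests. The age field of the embryos' labels rises by 1 step from sample to sample, starting at E13.5, while their titles all give E13.5, which was used.

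The files list 57683 features, of which 20031 are protein-coding genes and 36991 are NONCODE transcripts. Features with no exonic base of their own, outside all other features, number 6532 (6072 NONCODE, 370 coding) and hold no count, so Atp2a2, Sln, Xist and Meg3 could not be measured. H19 also held no count. A further 1999 coding genes have under 50% of their exonic bases to themselves, and 24845 NONCODE features overlap a coding gene.

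All statistics were computed from these counts in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and with DESeq2 1.42.0 as an alternative; figures used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. For each comparison, features were kept by edgeR's expression filter (minimum count 10, minimum total 15), scaled by TMM and tested with edgeR's quasi-likelihood test with robust dispersions. Benjamini-Hochberg adjusted p under 0.05 was called. E13.5 was set against the mean of the unoperated adult ages, 16 weeks against 6 weeks and TAC against sham. CPM are counts scaled to library size with TMM factors. Standard errors are the absolute log2 fold change over the square root of the F statistic. Genes without a count in a group were bounded against a floor of 3 counts over that group, and those with 1 to 3 counts were given a ratio with a 95% Poisson interval.

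In all, 31 gene lists fixed before the files were opened were tested with camera, at its preset correlation of 0.01 and with the correlation estimated from the data, where 3 or more members were tested. They were the fetal gene programme, adult contractile and calcium handling, extracellular matrix, fatty acid oxidation, oxidative phosphorylation, citric acid cycle, glycolysis and glucose uptake, cell cycle, cardiac transcription factors, imprinted growth genes, oncofetal RNA-binding and chromatin genes, potassium channels, mechanical stress and Z disc, circadian clock, immediate early and heat shock, interferon response, renin-angiotensin and natriuretic signalling and known lncRNAs. Markers were those of endothelial, smooth muscle, fibroblast, macrophage, lymphocyte, erythroid, atrial, epicardial, adipocyte, nerve, liver, lung and skeletal muscle cells.

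Named genes followed a rule fixed beforehand: the 10 called coding genes with the largest change in each direction, mean CPM of at least 5 and groups that did not overlap; the 4 lncRNA features with the largest change in each direction and mean CPM of at least 1; up to 4 called members of each list; and Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Postn, Igf2, H19 and Xist. Y-linked genes were left out of the TAC ranking. Further clock genes, X-linked and Y-linked genes and the neighbours of lncRNA features were named outside this rule. Overlap was tested with Fisher's exact test, and neighbouring pairs with 10000 shuffles. Some genes and features that met these rules, or that lay far from their group, are not reported here.

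On simulated counts with 200 changed features per comparison, edgeR recovered 79.1%, 100% and 98.5% of features changed 1.5-fold, 2-fold and 4-fold in the E13.5 comparison, 52.2%, 88.1% and 100% in the age comparison and 62.7%, 71.6% and 100% in the TAC comparison. False calls made up 3.65%, 2.44% and 5.45% of calls. The simulations left most features unchanged, whereas 10695 of 12766 features were called in the real E13.5 comparison and 5528 of 14555 in the real TAC comparison. These rates therefore do not carry over to those comparisons. Alternatives were RLE and upper-quartile scaling, DESeq2, limma-voom, no filter, a filter of at least 1 CPM in every library of a group, which kept more features than the main one in the E13.5 and age comparisons (16270 and 12574) and fewer in TAC (13704), all 27 libraries in 1 fit, a log2 fold threshold of 0.5, a replicate block, other adult references and each library left out. Chosen after seeing the data were fits without the libraries that went against their sex label, with Y-linked level as a covariate, without mitochondrial features, with embryonic libraries thinned to adult depth, and counts of lncRNA features overlapping no coding gene.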

Results

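Polyadenylated RNA was sequenced from 27 hearts of C57BL/6J mice, an inbred laboratory strain. Whole hearts came from 7 embryos at embryonic day E13.5. Ventricular apexes came from 6 unoperated adults at 6 weeks of age, 6 unoperated adults at 16 weeks, 4 sham-operated adults at 12 weeks and 4 adults at 12 weeks that had spent 4 weeks under transverse aortic constriction (TAC), a surgical narrowing of the aorta that loads the left ventricle with pressure. Each library was 1 heart, so replicate error was the spread between animals. Total counts per library ran from 7543375 to 12646039 at E13.5, from 2092270 to 2682955 at 6 weeks, from 2164604 to 2642307 at 16 weeks, from 7958592 to 11561952 in sham hearts and from 10411417 to 11846819 in TAC hearts. The unoperated adult libraries carried another base quality encoding in the labels than all the others, so their encoding and lower depth went with their group. On the first 2 principal components of log2 CPM (64.0% and 7.41% of the variance over 19204 features), the first component parted embryonic from adult hearts and the next parted the unoperated adults from the sham and TAC hearts.

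Y-linked transcripts did not follow the sex labels. Summed counts of Ddx3y, Kdm5d, Eif2s3y and Uty, which lie on the Y chromosome, were 3 or fewer in 7 of the 19 libraries labelled male, namely replicates 1 and 6 at 6 weeks, replicates 1 and 6 at 16 weeks, sham replicates 2 and 3 and TAC replicate 3. The TAC library labelled female had 389 Y-linked counts (37.4 CPM). The other male-labelled TAC libraries stood at 14.2 and 28.5 CPM, against 61.9 and 70.2 CPM in sham replicates 1 and 4. In each of the 7 libraries, the summed CPM of Kdm6a, Eif2s3x, Kdm5c and Ddx3x, X-linked genes known to escape X inactivation, lay above that of every library of its group with more than 3 Y-linked counts. Embryos were of unknown sex in the labels. Their Y-linked counts were 690 in replicate 3, 826 in replicate 6 and 6 or fewer in the others. The groups were kept as labelled, and counts without the libraries that went against their label are given with the comparisons of groups.

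**Figure D1:**
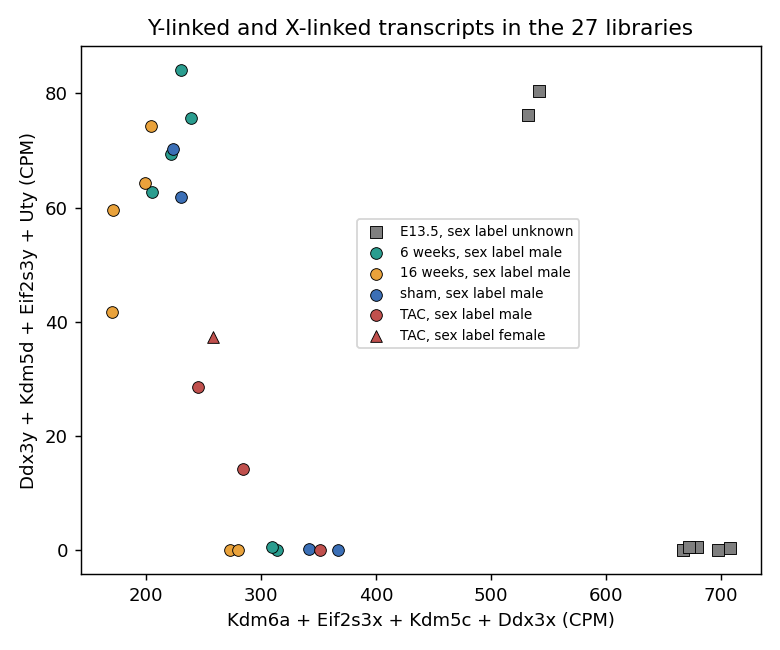
Each point is 1 library; the horizontal axis is the summed CPM of the X-linked genes Kdm6a, Eif2s3x, Kdm5c and Ddx3x and the vertical axis the summed CPM of the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty, with colour for the group and shape for the sex label. Of the 19 libraries labelled male, 7 lie at the bottom with 3 or fewer Y-linked counts, and the TAC library labelled female lies at 37.4 CPM.

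The comparison of embryonic with unoperated adult hearts asked which coding and noncoding transcripts distinguish the heart before birth from the mature heart. Embryonic hearts held far more RNA of cell division and growth genes, and far less of energy metabolism and mature contraction genes. Top2a, a topoisomerase of dividing cells, averaged 247 ± 17.9 CPM (SD, n = 7) at E13.5 against 2.41 ± 2.28 at 6 weeks (n = 6) and under 1 CPM at 16 weeks. Igf2, an imprinted fetal growth factor, averaged 4849 ± 483 CPM against 40.3 ± 11.2 at 6 weeks and 27.7 at 16 weeks. Mb, which encodes the oxygen-binding protein myoglobin, averaged 171 ± 25.1 CPM against 19448 ± 1078 and 21311 ± 1566 (n = 6 each). The myosin heavy chains changed in opposite directions: Myh7, the slow chain of the fetal ventricle, was higher (log2 fold change 1.58 ± 0.07, SE) and Myh6, the fast chain of the adult ventricle, was lower (-3.09 ± 0.09).

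By edgeR's quasi-likelihood test, 5630 features were higher and 5065 lower at E13.5 among 12766 tested (Benjamini-Hochberg adjusted p under 0.05), and 2806 and 2665 of these changed at least 2-fold. Groups did not overlap for 6984 of the 12766 features tested, where chance gives 0.00397% per feature. Several of the strongest embryonic transcripts had no count in any of the 12 adult libraries, and their folds are lower bounds against a floor of 3 counts over the adult group. Hbb-y, an embryonic beta-like globin, was at least 116470-fold higher, Hba-x, an embryonic alpha-like globin, at least 39564-fold, and Hbb-bh1 at least 870-fold. Igf2bp1, an oncofetal RNA-binding protein gene with 47.0% of its exonic bases outside other genes, was at least 1084-fold higher. Bmp10, a growth factor of the embryonic heart, was at least 561-fold higher, Igfbp2 at least 494-fold, Dgkk at least 442-fold and the transcription factor gene Sox11 at least 338-fold. Bmp10 is on the atrial marker list, and the adult samples were ventricular apexes, so stage could not be told apart from region for it. Hsd3b6 had 1 count in the adult libraries and a ratio of 6900 (95% counting interval 1238 to 272530). Tnni1, the slow skeletal troponin I of the fetal heart, rose by 11.72 ± 0.15 on the log2 scale (adjusted p = 8.07e-32). On the lower side, the log2 fold change was -9.79 ± 0.19 for Rpl3l, a muscle-specific ribosomal protein gene, -9.48 ± 0.13 for Ckmt2, the mitochondrial creatine kinase of muscle, -8.79 ± 0.26 for Xirp2, -8.74 ± 0.19 for Myom2, an M-band protein gene, and -8.73 ± 0.32 for Xdh. Ces3, Tuba8, Mylk4 and Myot had log2 fold changes of -9.53, -9.41, -9.18 and -8.99. Pdha2 had no count in any embryonic library and was at least 255-fold lower. The natriuretic peptide genes differed: Nppb fell by 1.48 ± 0.41 (adjusted p = 0.00277), and Nppa (log2 fold change 0.42 ± 0.33, adjusted p = 0.25) did not pass. Acta1, skeletal alpha-actin, did not pass either (0.07 ± 0.50, adjusted p = 0.903), and Postn, a matricellular protein gene, rose by 3.24 ± 0.19.

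Of the gene lists fixed before the data were examined, cell division and growth lists were higher at E13.5. All 36 tested cell cycle genes rose, with a median log2 fold change of 5.73, including Top2a (7.63 ± 0.19), and Ccnb1, cyclin B1, was at least 93.0-fold higher. All 12 tested imprinted growth genes rose (median 3.81), among them Mest (7.47 ± 0.12), Igf2 (7.18 ± 0.11) and Plagl1 (6.57 ± 0.09). Of 14 oncofetal RNA-binding and chromatin genes, 13 rose and 1 did not pass, with Igf2bp3 at 7.11 ± 0.17 and Uhrf1 at 6.23 ± 0.17. All 9 epicardial markers rose, including Krt19 (5.63 ± 0.18) and Upk3b (6.22 ± 0.18). The preset camera test gave adjusted p-values of 1.29e-35, 4.47e-18, 1.46e-09 and 2.49e-05 for these lists, and each kept its call with an estimated correlation (adjusted p = 9.78e-04, 1.83e-06, 0.00114 and 0.00667). Energy lists were lower. Of 32 fatty acid oxidation genes 31 fell, including Acsl1 (-5.16 ± 0.08), which activates long-chain fatty acids, and Cd36 (-4.92 ± 0.18), which takes them up. Of 42 oxidative phosphorylation genes 41 fell, including the heart and muscle cytochrome oxidase subunits Cox8b (-5.78 ± 0.10) and Cox6a2 (-4.25 ± 0.09). All 19 citric acid cycle genes fell, including Ogdh (-3.24 ± 0.06). Among 23 adult contractile and calcium handling genes 22 fell and Slc8a1, the sodium-calcium exchanger (43.1% of exonic bases outside other genes), rose by 0.39 ± 0.09. Among 18 potassium channel genes 17 fell, with Kcnip2 at -8.47 ± 0.24, and Kcne1 rose by 2.81 ± 0.17. These lists had camera adjusted p-values of 4.38e-26, 8.12e-31, 2.64e-15, 1.45e-19 and 1.29e-08, and they kept their calls with an estimated correlation (adjusted p = 0.00163, 9.78e-04, 0.00651, 9.19e-04 and 9.78e-04).

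Further lists passed only with the preset correlation. In the fetal gene programme 8 of 13 members rose and 3 fell (adjusted p = 0.0069, and adjusted p = 0.0797 with an estimated correlation), with Myl7, the atrial light chain, at 9.65 ± 0.48 and Tnnt2 at -1.73 ± 0.06. Myl7 stood at 25.6 CPM in 6-week replicate 2 and at 1.44 or less in the other adults, and its log2 fold change was 12.32 without that library. Among 36 extracellular matrix genes 22 rose and 12 fell (0.00478, and adjusted p = 0.334 with an estimated correlation), with Tnc at 4.89 ± 0.16 and Dcn at -3.17 ± 0.19. The mechanical stress and Z disc list had 3 members higher and 13 lower of 19 (1.33e-04, and adjusted p = 0.239 with an estimated correlation), and the renin-angiotensin and natriuretic signalling list 2 higher and 11 lower of 15 (0.028, and adjusted p = 0.0592 with an estimated correlation). Markers of other cells moved too, and whole embryonic hearts were set against adult ventricular apexes. All 11 erythroid markers rose (8.63e-04, and adjusted p = 0.353 with an estimated correlation), 7 of 11 atrial markers rose and 2 fell (0.0144, and adjusted p = 0.237 with an estimated correlation), 12 of 13 macrophage markers fell and 1 rose (0.0178, and adjusted p = 0.296 with an estimated correlation), and 10 of 13 endothelial markers fell and 2 rose (0.0269, and adjusted p = 0.124 with an estimated correlation). Glycolysis and glucose uptake genes went both ways (8 higher, 10 lower, 2 not passing of 20; camera adjusted p = 0.0907): Slc2a1, the fetal glucose transporter, rose by 3.61 ± 0.09 while Slc2a4, the insulin-responsive transporter, fell by 4.52 ± 0.09. The cardiac transcription factor list also went both ways (8 higher and 7 lower of 20; 0.344), with Tbx18 at 3.41 ± 0.14 and Hopx at -1.91 ± 0.09. All of the counts for lists in this comparison were equal when adjusted over the list alone.

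**Figure D2:**
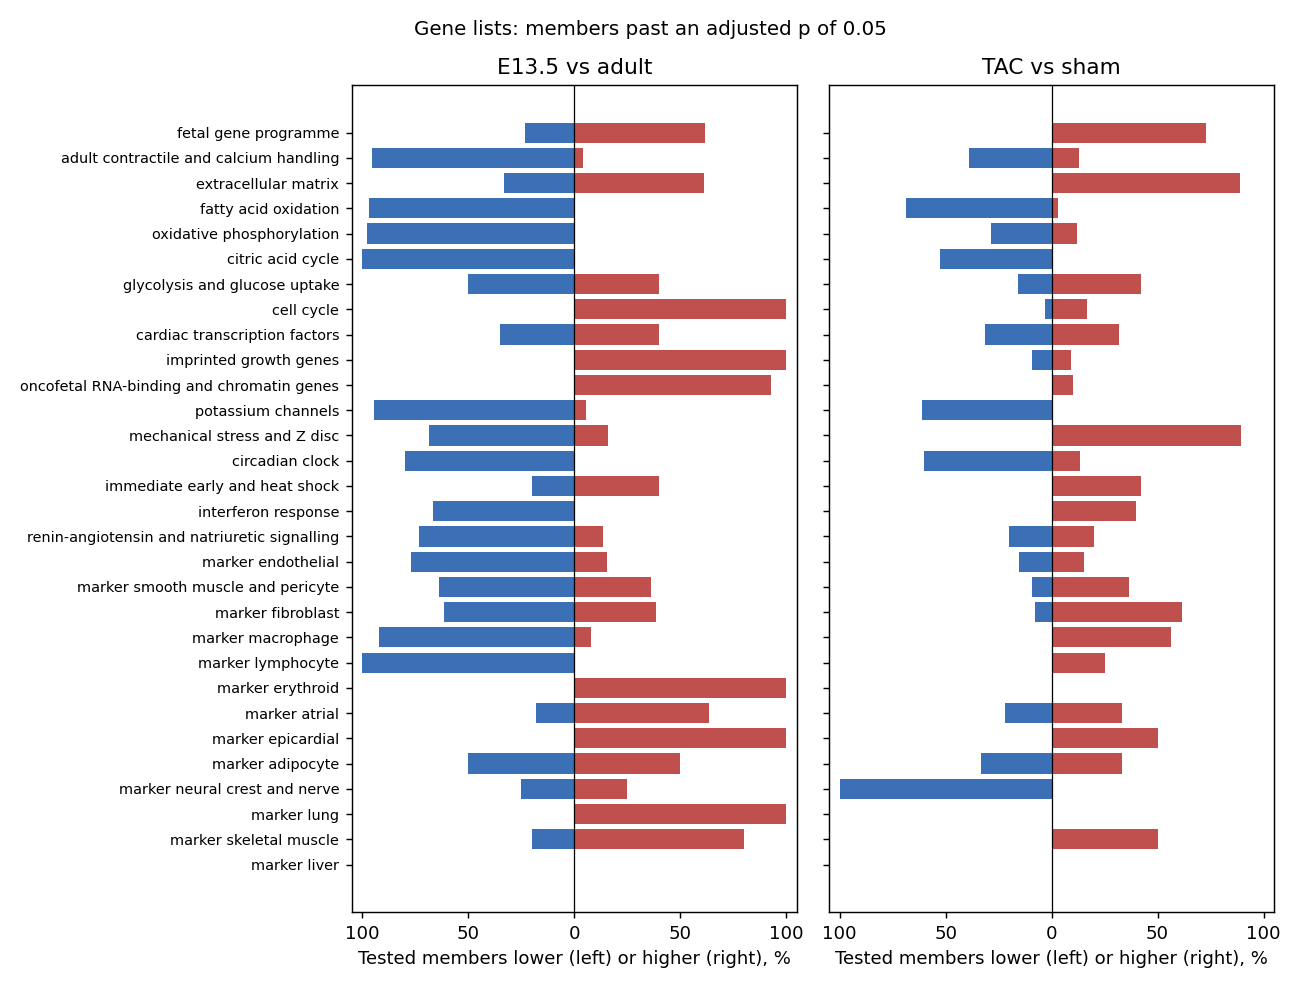
Bars give the percentage of tested members of each gene list that were higher (red, to the right) or lower (blue, to the left) at an adjusted p under 0.05 in E13.5 against adult hearts and in TAC against sham hearts. Oxidative phosphorylation had 41 of 42 members lower at E13.5, and extracellular matrix had 32 of 36 members higher in TAC.

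Noncoding features, taken by the authors from the NONCODE collection of long noncoding RNAs (lncRNAs), changed in both directions: of 1552 tested, 680 were higher and 524 lower at E13.5. These counts depended on the filter, the reference and the depth: they were 1771 and 907 when features with at least 1 CPM in every library of a group were kept, 2345 and 1332 against sham hearts, and 523 and 485 with embryonic libraries thinned to adult depth. Of the 680 and 524, 183 and 203 overlapped no coding gene. Features with large increases included n419655 (chromosome 2, 40412523 to 40412802), at least 108-fold higher, n278131, which lies 986 bases from Gata5 (ratio 345, 95% counting interval 61.9 to 13627), and n271101, which overlaps Pif1 (at least 49.4-fold). Among the lower ones, n287430 lay 2045 bases from Mylk4 (-8.85 ± 0.28) and n289091 lay 3196 bases from Adra1a (-7.61 ± 0.38), and both of these neighbours fell as well (Mylk4 -9.18, Adra1a -6.64). The libraries were not strand-specific, so reads of a feature and of a gene overlapping it on the other strand could not be told apart.

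Stage could not be told apart from base quality encoding, or from whole heart against ventricular apex, within this comparison. With embryonic libraries thinned to adult depth, 5209 features were higher and 4938 lower, and 127 of 127 values of named genes kept their direction and call. Without the 4 adult libraries that went against their sex label, 5707 features were higher and 5064 lower. That fit kept only adults with more than 3 Y-linked counts, while most embryos had few, so it did not balance sex between stages. With Y-linked level as a covariate, 128 of 128 values of named genes kept their direction and call. Against sham hearts, which shared the encoding of the embryonic libraries, 7597 features were higher and 6657 lower, 9393 of the 10695 called features passed in the same direction and 154 in the opposite one, oxidative phosphorylation had 42 of 42 members lower and imprinted growth genes 12 of 12 higher, but Acta1 turned to -0.76 (adjusted p = 5.83e-06), Nppa passed at 2.18 (2.29e-14) and Myh7 stood at 4.11.

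The comparison of 16-week with 6-week hearts asked what changes while the young adult heart matures. Few features differed. Ndrg4, a gene of the heart and nervous system, fell from 705 ± 51.4 CPM at 6 weeks to 333 ± 29.8 at 16 weeks (SD, n = 6 each; log2 fold change -1.08 ± 0.07, edgeR adjusted p = 1.67e-09). Hcn4, the pacemaker channel, fell by 1.10 ± 0.23 (adjusted p = 0.0181) and Trdn, a calcium release complex protein gene, by 0.88 ± 0.20 (0.0458). On the extracellular matrix list, the genes called lower at 16 weeks were Sparc (-0.52 ± 0.08, adjusted p = 0.00141), Mfap5 (-0.66 ± 0.15, 0.0171), Loxl2 (-0.54 ± 0.14, 0.0388) and Col1a2 (-0.39 ± 0.10, 0.0333). In the 12 fits that each left out 1 library, Mfap5, Loxl2 and Col1a2 lost their calls in 2, 7 and 6.

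In all, 137 features were higher and 124 lower at 16 weeks among 10394 tested, and 11 and 17 of these changed at least 2-fold. Groups did not overlap for 212 of the 10394 features tested, where chance gives 0.216% per feature. The coding genes with the largest increases were Bbs2 (1.20 ± 0.20), a ciliary protein gene, Gnb3 (1.18 ± 0.29), Cnga3 (1.07 ± 0.29), BC018242 (0.95 ± 0.19), Peli3 (0.95 ± 0.19), Sncg (0.93 ± 0.19), Htatip2 (0.91 ± 0.19), Hspa2 (0.87 ± 0.22), Cd274 (0.84 ± 0.22) and Hba-a2 (0.84 ± 0.19). Hba-a2 has a near-identical copy, so its counts are uncertain. Among the largest decreases were Uqcrb (-2.40 ± 0.46), a complex III subunit gene, and Snap91 (-2.23 ± 0.36), followed by Hcn4, Ndrg4, Xaf1 (-0.98 ± 0.24), Sv2a (-0.94 ± 0.19), Trdn, Wfdc1 (-0.88 ± 0.17) and Fundc2 (-0.86 ± 0.17). Uqcrb was uneven among 16-week hearts, at 3.02 ± 3.94 CPM, and without 16-week replicate 5 its log2 fold change was -3.44. Of the 12 fits that each left out 1 library, Gnb3, Cnga3, Hspa2, Cd274 and Hba-a2 lost their calls in 9, 11, 8, 10 and 9, Trdn in 10, Xaf1 in 6 and Hcn4 in 3. None of the cardiac stress genes Nppa (0.77 ± 0.52, adjusted p = 0.505), Nppb (0.34 ± 0.61, 0.839), Acta1 (-0.25 ± 0.80, 0.916), Myh6 (0.05 ± 0.08, 0.834), Myh7 (0.19 ± 0.07, 0.145) and Postn (-0.98 ± 0.34, 0.172) passed, and neither did Igf2 (-0.55 ± 0.16, 0.0627). Among 811 lncRNA features 5 were higher and 21 lower, with n291524 at 1.55 ± 0.29 and n282476, 7699 bases from Igf2r, at -1.52 ± 0.28.

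By list, extracellular matrix had 4 of 31 members lower and none higher, or 12 lower when adjusted over the list alone (camera adjusted p = 6.59e-07, and adjusted p = 0.373 with an estimated correlation). With 1 library left out, the number called lower ran from 2 to 12. Fibroblast markers, some of which are also on the matrix list, had 3 of 13 lower, or 4 adjusted over the list alone (0.00322, and adjusted p = 0.373 with an estimated correlation), namely Mfap5, Col1a2 and Dpt (-0.58 ± 0.14). With 1 library left out, this count ran from 1 to 5, and Dpt lost its call in 10 of the 12 fits. Macrophage markers shifted down as a list (13 tested; 0.0217, and adjusted p = 0.414 with an estimated correlation) without a called member, and shares of cell types were not measured. The mechanical stress and Z disc list had 3 members higher and 1 lower of 19, or 8 and 1 adjusted over the list alone (1.95e-05, and adjusted p = 0.373 with an estimated correlation), including Hspb7 (0.55 ± 0.13) and Fhl2 (-0.34 ± 0.07). Imprinted growth genes had 3 of 10 lower, or 5 adjusted over the list alone (0.00274, and adjusted p = 0.108 with an estimated correlation), namely Plagl1 (-0.97 ± 0.22), Peg3 (-0.53 ± 0.14) and Grb10 (-0.35 ± 0.09). Cardiac transcription factors had 2 of 18 higher, or 3 adjusted over the list alone (0.00607, and adjusted p = 0.115 with an estimated correlation), Hand2 (0.43 ± 0.09) and Prox1 (0.34 ± 0.09). With 1 library left out, Hspb7 and Peg3 each lost their call in 10 fits, Grb10 in 9, Prox1 in 7, and Plagl1 and Hand2 in 1 each. The number higher ran from 0 to 3 for the Z disc list and for cardiac transcription factors, and the number lower from 1 to 2 for imprinted growth genes. Oxidative phosphorylation had 1 of 42 members lower, fatty acid oxidation 1 of 32 higher, Slc27a1, which lost its call in 8 of those fits, and the citric acid cycle 1 of 19 higher, Idh2 (0.38 ± 0.06). Adjusted over the list alone, the counts higher and lower were 1 and 2, 1 and 0, and 1 and 3, and camera called none of these lists (0.0573, 0.916 and 0.31).

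The counts depended on single libraries. Without replicate 4 or 5 at 6 weeks, or replicate 1, 3, 4 or 6 at 16 weeks, 81, 75, 72, 51, 63 and 80 features were higher and 61, 73, 72, 56, 57 and 74 lower; without replicate 6 at 6 weeks 207 were higher, and without the 4 libraries that went against their sex label 74 were higher and 64 lower, with 1 extracellular matrix gene lower. In that last fit Mfap5, Col1a2 and Loxl2 stood at -0.65 ± 0.19, -0.44 ± 0.12 and -0.40 ± 0.17, so their calls ended mostly with wider errors for Mfap5 and Col1a2 and with a smaller fold as well for Loxl2. Gnb3, Cnga3, Peli3, Hspa2, Cd274, Hba-a2, Uqcrb, Hcn4, Xaf1, Trdn, Wfdc1 and Fundc2 lost their calls there too. So did Hspb7, Peg3, Grb10, Plagl1, Hand2, Prox1, Dpt and Slc27a1. Their folds moved both ways, as for Gnb3 (1.18 to 1.36) and Slc27a1 (0.33 to 0.24).

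The comparison of TAC with sham hearts asked how the adult heart responds to pressure overload. TAC hearts held more RNA of stress and fibrosis genes. Acta1, skeletal alpha-actin, averaged 7635 ± 2886 CPM in TAC against 324 ± 64.9 in sham hearts (SD, n = 4 each), 23.5-fold higher by the fit. Nppa, atrial natriuretic peptide, averaged 2564 ± 519 CPM against 188 ± 13.4 (13.6-fold) and Nppb, brain natriuretic peptide, 550 ± 132 against 159 ± 62.2 (3.46-fold). Myh7, the slow myosin heavy chain, averaged 2139 ± 738 against 394 ± 4.01 (5.43-fold), while Myh6 averaged 56628 ± 5375 against 58545 ± 6526 (log2 fold change -0.05 ± 0.09, edgeR adjusted p = 0.699). In the age comparison, scaled apart, unoperated adults stood at 2193 to 3185 CPM of Myh7. TAC hearts thus lay above sham hearts in Myh7 but not above unoperated adults, for which encoding, age and surgery differed together. Postn averaged 131 ± 50.1 CPM against 23.4 ± 1.56 (5.63-fold). Potassium channel, fatty acid oxidation and clock genes were mostly lower, as detailed by list.

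**Figure D3:**
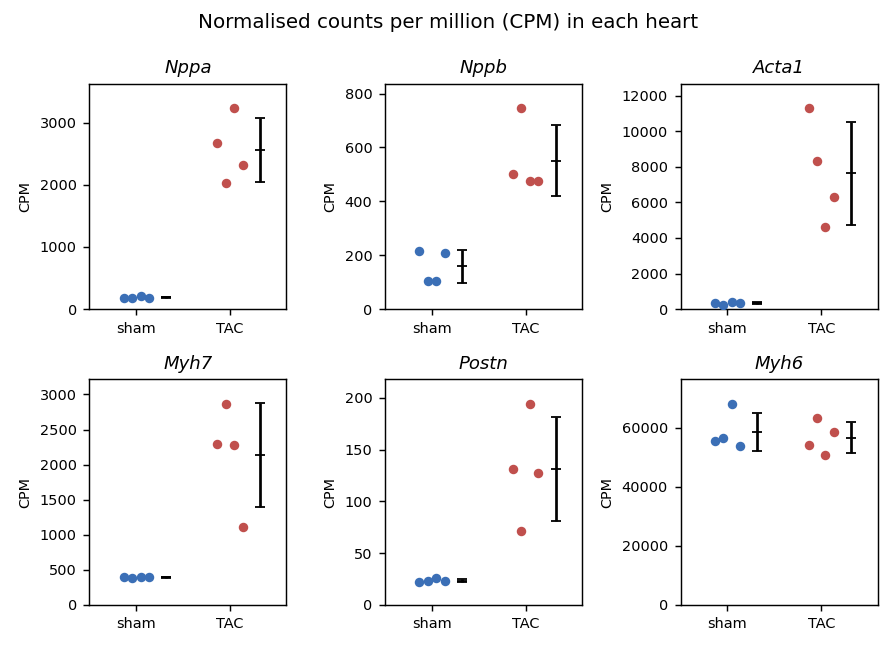
Points are CPM, scaled by TMM factors, of Nppa, Nppb, Acta1, Myh7, Postn and Myh6 in each of the 4 sham and 4 TAC hearts, with axes starting at 0; the black bar beside each group is its mean with the SD. The TAC hearts lie above all sham hearts for every gene but Myh6, whose groups overlap.

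By edgeR's quasi-likelihood test, 2847 features were higher and 2681 lower in TAC among 14555 tested, and 433 and 642 of these changed at least 2-fold. Groups did not overlap for 5169 of the 14555 features tested, where chance gives 2.86% per feature. Among coding genes 2735 were higher and 1650 lower. Among the largest increases were Egr2 (log2 fold change 4.72 ± 1.09, adjusted p = 0.0166), an immediate early transcription factor, and Acta1 (4.56 ± 0.35, 1.69e-04), followed by the matrix genes Ltbp2 (4.44 ± 0.30), Fmod (4.40 ± 0.45), Thbs4 (4.12 ± 0.40), Comp (4.07 ± 0.39), Cilp (3.97 ± 0.35) and Thbs1 (3.60 ± 0.56), with Nppa at 3.77 ± 0.14 (5.39e-08). Without TAC replicate 2, Egr2 stood at 3.70, below Acta1, and Thbs1 at 3.03. The largest decreases were in Pfkfb1 (-2.50 ± 0.15, adjusted p = 8.87e-08), a regulator of glycolysis, mt-Nd3 (-2.26 ± 0.46, 0.00658), a mitochondrially encoded complex I subunit, Ppl (-1.90 ± 0.21), and Hlf (-1.83 ± 0.12, 5.39e-08), a clock output transcription factor. Cenpf, Ccbe1, Ces3, Kcnv2, Spna1 and Lgals4 had log2 fold changes of -1.79, -1.58, -1.56, -1.54, -1.54 and -1.53, and Spna1 lost its call in 5 of the fits that left out 1 library. Igf2, which was far higher in embryos, fell by 0.82 ± 0.17 (0.00206). Mitochondrial transcripts took 1.57% ± 0.27 of counts in TAC and 5.05% ± 2.21 in sham hearts, where replicate 2 stood at 1.77%.

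Stress and matrix lists were higher in TAC. In the fetal gene programme 8 of 11 tested members rose and none fell (camera adjusted p = 2.07e-09, and adjusted p = 0.0285 with an estimated correlation), including Ankrd1 (1.99 ± 0.35). Of 36 extracellular matrix genes 32 rose, or 33 adjusted over the list alone, and none fell (5.47e-43, and adjusted p = 0.0422 with an estimated correlation). Of 19 mechanical stress and Z disc genes 17 rose, including Rcan1 (1.85 ± 0.13), a calcineurin target, and Fhl1 (1.17 ± 0.19), with 3.73e-15 and adjusted p = 0.0604 with an estimated correlation. Of 13 fibroblast markers 8 rose, including Col1a1 (1.90 ± 0.22) and Mfap5 (1.87 ± 0.10), and Ddr2 fell by 0.47 ± 0.09 (1.85e-05, and adjusted p = 0.22 with an estimated correlation). Of 16 macrophage markers 9 rose, or 13 adjusted over the list alone, including Lgals3 (1.42 ± 0.33) and Cx3cr1 (1.36 ± 0.19), with 3.76e-05 and adjusted p = 0.334 with an estimated correlation. Of 19 immediate early and heat shock genes 8 rose, or 10 adjusted over the list alone (0.00117, and adjusted p = 0.334 with an estimated correlation). Of these, Hspa1b and Nr4a1 each lost their call in 5 of the 8 fits that left out 1 library, Egr2 in 2 and Junb (1.61 ± 0.38) in 1. In those fits the number of immediate early and heat shock genes called higher ran from 4 to 10.

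The potassium channel, fatty acid oxidation, citric acid cycle and clock lists were lower by the preset camera test. Of 18 potassium channel genes 11 fell and none rose (7.61e-06, and adjusted p = 0.0285 with an estimated correlation), including Kcnj2 (-1.45 ± 0.14), the inward rectifier, and Kcnd2 (-1.23 ± 0.16). Of 32 fatty acid oxidation genes 22 fell and 1 rose, or 23 and 2 adjusted over the list alone (1.69e-07, and adjusted p = 0.248 with an estimated correlation), including Cd36 (-0.72 ± 0.09) and Lpl (-0.70 ± 0.07), while Cpt1b rose by 0.52 ± 0.09 with only 5.22% of its exonic bases outside other genes. Of 19 citric acid cycle genes 10 fell (8.77e-04, and adjusted p = 0.445 with an estimated correlation), including Dld (-0.69 ± 0.08). Of 42 oxidative phosphorylation genes 12 fell and 5 rose, or 13 and 5 adjusted over the list alone (0.114). Of 23 adult contractile and calcium handling genes 9 fell and 3 rose, or 9 and 4 adjusted over the list alone (0.103), with Ttn at -0.91 ± 0.10, Pln, phospholamban, at -0.90 ± 0.11 and Mybpc3 at 0.52 ± 0.07. Of 15 circadian clock genes 9 fell and 2 rose (2.62e-06, and adjusted p = 0.0515 with an estimated correlation). Those that rose were Arntl (3.10 ± 0.31, adjusted p = 3.00e-05) and Npas2 (1.94 ± 0.25, 4.38e-05), transcription factors of the positive arm of the clock, and those that fell included Hlf and Per3 (-1.44 ± 0.11, 1.27e-07, 34.7% of exonic bases outside other genes). All 4 tested nerve and neural crest markers fell, including S100b, Dbh and Sox10 with log2 fold changes of -1.08, -0.99 and -0.98 (0.0293, and adjusted p = 0.2 with an estimated correlation), and S100b and Dbh lost their calls in 3 and 2 of the fits that left out 1 library. Glycolysis and glucose uptake had 8 members higher and 3 lower of 19 (0.019, and adjusted p = 0.445 with an estimated correlation), with Pfkp at 0.98 ± 0.10 and Slc2a4 at -0.38 ± 0.08. Where no second count is given, the counts were equal when adjusted over the list alone. With 1 library left out, 9 to 18 oxidative phosphorylation genes fell and 3 to 5 rose. For contractile genes 7 to 9 fell and 3 to 5 rose, and for glycolysis genes 1 to 3 fell and 8 to 9 rose.

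**Figure D4:**
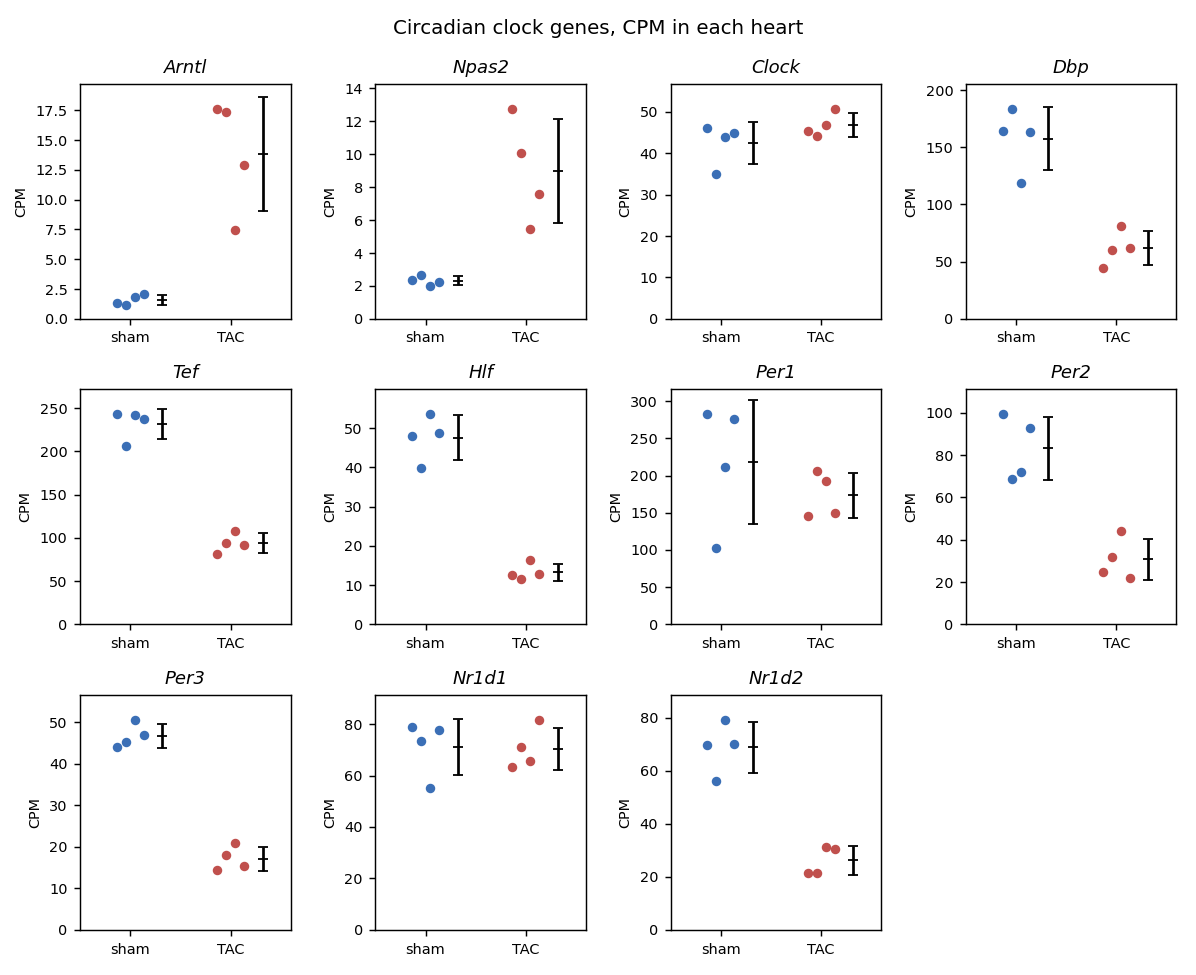
Points are CPM, scaled by TMM factors, of 11 circadian clock genes in each of the 4 sham and 4 TAC hearts, with axes starting at 0; the black bar beside each group is its mean with the SD. Arntl and Npas2 lie higher in all TAC hearts and Dbp, Tef, Hlf, Per2, Per3 and Nr1d2 lower, while Clock (adjusted p = 0.237), Per1 (0.481) and Nr1d1 (0.893) did not pass.

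Noncoding features in TAC went mostly down: of 2894 tested, 107 were higher and 1025 lower. Among those overlapping no coding gene 57 were higher and 205 lower, and among those overlapping a coding gene 50 and 820. The largest increases were in n264397 (2.38 ± 0.40), n283525, which lies 7025 bases from S1pr1 (1.96 ± 0.36), n277166 (1.90 ± 0.26, only 2.53% of exonic bases outside other genes) and n297276, which overlaps Ankrd23 (1.86 ± 0.26). The largest decreases were in n269772 (-3.90 ± 0.42), n287177, 6031 bases from Neu4 (-3.49 ± 0.50), n286883, which overlaps Slc16a10 (-2.78 ± 0.37), and n278873 (-2.73 ± 0.34).

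Without the libraries that went against their sex label, which left 2 hearts per group, 2659 features were higher and 2461 lower and 29 of 36 extracellular matrix genes rose. In that fit Nppa, Acta1 and Myh7 kept their calls, while Postn (adjusted p = 0.0621), Cilp (0.0631), Ltbp2 (0.0593), Thbs1 (0.076), Thbs4 (0.0884) and Egr2 (0.0994) did not. Their log2 fold changes, 2.49 ± 0.31, 3.97 ± 0.35, 4.44 ± 0.30, 3.60 ± 0.56, 4.12 ± 0.40 and 4.72 ± 1.09 with all 8 hearts, were 2.17 ± 0.44, 4.02 ± 0.71, 4.46 ± 0.78, 3.98 ± 0.79, 4.25 ± 0.93 and 5.52 ± 1.32 in that fit. The folds stayed large while the standard errors grew with fewer hearts, so these lost calls do not show that the libraries left out carried the changes. The folds of Cnn1 (0.88 ± 0.30, and 0.10 ± 0.22 in that fit) and Cdca8 (0.87 ± 0.33 and 0.21 ± 0.42) did shrink as their calls ended. Among other lost calls, Cdc20 (0.79 to 0.48), Oas1a (0.84 to 0.61), Cspg4 (0.46 to 0.29) and Eno3 (-0.19 to -0.13) shrank too. Junb (1.61 to 1.67) and Nr4a1 (1.88 to 2.12) did not shrink.

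Whether pressure overload moved the adult heart toward the embryonic pattern was asked from the overlap of these comparisons, which share no library. Among 12155 features tested in both, 1201 were higher in both TAC and E13.5 hearts, where independent lists give 1096 (Fisher's exact test, odds ratio 1.23, p = 3.06e-06). The excess over independent lists was larger among lower features: 1187 were lower in both, against 868 for independent lists (Fisher's exact test, odds ratio 2.11, p = 7.43e-54). Fisher's tests here count features, which are not independent replicates, so their p-values do not measure the spread between animals. Among NONCODE features alone, 26 were higher in both against 26.7 for independent lists (Fisher's exact test, odds ratio 0.958, p = 0.9) and 242 lower against 186 (odds ratio 2.07, p = 2.17e-10). With the TAC comparison fitted without the libraries that went against their sex label, 1066 were higher in both (Fisher's exact test, odds ratio 1.10, p = 0.033) and 1076 lower (odds ratio 2.12, p = 4.59e-50). Of features higher in TAC, 1055 were lower at E13.5, against 1097 for independent lists. Of features lower in TAC, 547 were higher at E13.5, against 866. Of the 3990 features called in both, 59.9% went the same way, and across genes, which are not independent replicates, the log2 fold changes had Pearson's r of 0.19 and Spearman's rho of 0.15. Single genes went both ways: Myh7 and Postn were higher in both, Igf2 was higher at E13.5 and lower in TAC, and Cilp was higher in TAC and lower at E13.5. With sham hearts as the embryonic reference the overlaps were 1111 and 1753, but those comparisons share the sham libraries. In 10 simulations of unchanged groups set against them, a mean of 0.2 features passed in the same direction in both. The shared libraries alone gave a simulated Pearson's r of 0.585. Those simulated groups held no real change, so that r cannot be set against the 0.265 observed with that reference. The simulated covariance was 0.0231 against 0.25 observed. With the sham libraries divided between the comparisons, the overlaps were 820 and 1320, the covariance 0.244 and Pearson's r 0.22.

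The last comparison set each lncRNA feature beside its nearest coding gene 5 to 50 kb away. In E13.5 against adult hearts, the log2 fold changes of 98 such pairs went together (Spearman's rho 0.45, permutation p = 1e-04, the smallest that 10000 shuffles can give; mean product 1.55 against -0.00281 when neighbours were shuffled, p = 2e-04), and 47 of 62 pairs called in both members went the same way. In TAC against sham hearts, 167 pairs gave a rho of 0.11 (permutation p = 0.142), and 14 of 21 pairs called in both members went the same way. Pairs 1 to 20 kb apart gave a rho of 0.25 in TAC (1e-04), pairs 5 to 100 kb apart 0.16 (0.0345) and overlapping pairs 0.32 (1e-04). The shuffles count pairs, which are not independent replicates, so their p-values do not measure the spread between animals.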

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

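The tests of TAC depth and of too few reads were chosen only after the result was seen; the other tests of the 3 patterns below were chosen after the pattern was seen but before the value that each test measures.

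NONCODE features fell far more often than they rose in TAC against sham hearts, with 1025 lower and 107 higher. Lower depth of the TAC libraries is argued against by the mean total count, which was 1.1027 times that of sham libraries. Fewer reads from introns of coding genes stays open: NONCODE features inside a coding gene without exonic overlap fell even where that gene was called higher (median -0.47365, 95% interval -0.58 to -0.39, 151 features), which does not exclude regulated change of the features themselves. A change of lncRNA genes apart from coding genes stays open. Multi-exon features overlapping no coding gene had a median of -0.2793, below the -0.2 set before that median was seen. Its 95% interval (-0.37 to -0.19) reached past -0.2, so this was left undecided. Both intervals resampled features and not hearts, so they do not measure the spread between animals. These explanations can hold together.

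Clock output genes differed between TAC and sham hearts. A single outlying library is argued against, since 10 or more clock genes passed with any library left out, against 11 with all libraries. Hearts taken at different times of day stay open as a hypothesis: Arntl, Npas2 and Clock, of the opposing arm, had a median of 1.9425 (3.10, 1.94 and 0.14), while Dbp, Hlf, Per2, Per3 and Nr1d2 had log2 fold changes of -1.35, -1.83, -1.44, -1.44 and -1.39. Tef also fell, whereas Clock, Per1 (-0.33) and Nr1d1 (-0.02) did not pass. The times at which hearts were taken are not given in the sources used here, and an effect of TAC on the clock was not tested apart from time of day.

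Y-linked transcripts did not follow the sex labels. Too few reads to detect them is argued against, since at the lowest level of the other libraries of each group at least 100.51 counts were due in each low library. Sex labels that do not describe the animals sequenced stay open as a hypothesis, since in 7 of 7 such libraries the X-linked genes lay above every library of the group with more than 3 Y-linked counts. The wording set before, above every other library of the group, could not be met by 2 such libraries of the same group. Mixed RNA was not tested, and the library labelled female, with 389 Y-linked counts, was noted as a signal outside the main measurement.

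Other divisions of the libraries into groups of the same sizes were fitted too. In the E13.5 comparison, with adult ages merged, 1 of 100 splits, the real one, gave as many calls (10412; highest other 4910, which set 7 adults against the other 5 adults and all 7 embryos and so follows the stage). In the age comparison this was 1 of 100 (261; highest other 164) and in the TAC comparison 1 of 35 (5528; highest other 0 by edgeR, with up to 2060 at unadjusted p under 0.05 against 6837 for the real groups), so chance division of the libraries is excluded at 0.05 for each.

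Libraries far from the rest of their group were sought in 762 profiles of library measures and named genes. Chance picks out about 1 in 20 groups of normally distributed values, or 38.1 here, and 73 were picked out. A lone value above 0 in a group of zeros, as for Hsd3b6 in 6-week replicate 1, is always picked out. Some genes of the unoperated adults were screened in both the E13.5 and the age comparison. The 73 therefore cannot be set against the 38.1. NONCODE features took 5.978% of counts in E13.5 replicate 2 and 4.186% in sham replicate 2, mitochondrial transcripts 1.774% in sham replicate 2, and the top 10 features 16.059% in 16-week replicate 5. The values that follow are CPM.

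In E13.5 against adult hearts, the following lay far from their group. E13.5 replicate 4 stood apart in Hbb-y 33445, Hba-x 9272.8, Hsd3b6 618.31, Hbb-bh1 209.25 and Epb4.2 41.14. 6-week replicate 1 stood apart in Hsd3b6 0.43, Cdc2a 3.9 and Hopx 372.65. E13.5 replicate 1 stood apart in Xdh 0.79. 16-week replicate 3 stood apart in n278131 0.55. E13.5 replicate 6 stood apart in n271101 4.5. E13.5 replicate 5 stood apart in n295438 0.09. 6-week replicate 2 stood apart in Myl7 25.64, Dcn 830.12, Ucp3 136.9, Igf2 62.59 and Car3 26.51. E13.5 replicate 3 stood apart in Col12a1 230.42, Col1a1 2369, Cx3cr1 32.32, Igh-6 4.93 and Tubb3 40.92. 6-week replicate 6 stood apart in Mdh1 2185.6 and Bub1 0.56. 16-week replicate 4 stood apart in Mest 5.03, Pdlim3 47.74, Dpt 72.36, Ager 1.51 and Acta1 652.26. E13.5 replicate 2 stood apart in Plagl1 1036.4. 16-week replicate 5 stood apart in Plagl1 11.04 and Krt8 1.92. 6-week replicate 3 stood apart in Hmga2 0.5. E13.5 replicate 7 stood apart in Hspb1 124.58 and Cd14 1.68. 16-week replicate 6 stood apart in Dusp1 387.63, Ier3 51.59, Epb4.2 0.46 and Mylpf 0.46. 16-week replicate 1 stood apart in Irf7 7.51. 6-week replicate 5 stood apart in Tubb3 2.72.

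In 16-week against 6-week hearts, the following lay far from their group. 16-week replicate 3 stood apart in Cnga3 10.91. 16-week replicate 4 stood apart in Sncg 27.6, Cenpf 54.34, Dpt 61.14 and Acta1 551.07. 6-week replicate 2 stood apart in Hba-a2 39.45, Cenpf 222.18, Hspb7 2583.9 and Igf2 53.59. 16-week replicate 5 stood apart in Uqcrb 10.72, Plagl1 9.49 and Grb10 186.85. 6-week replicate 6 stood apart in n265259 6.28. 6-week replicate 4 stood apart in n282476 16.78. 16-week replicate 6 stood apart in Dusp1 328.52.

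In TAC against sham hearts, the following lay far from their group. Sham replicate 3 stood apart in Comp 1.98. TAC replicate F1 stood apart in Lpl 1979.3 and Flt1 234.66. Sham replicate 2 stood apart in Dld 135.39 and Isg15 7.75. TAC replicate 2 stood apart in Sdhc 489.24 and Nppb 747.25. Sham replicate 4 stood apart in Srf 183.26. TAC replicate 3 stood apart in Hspa1b 29.33, Col3a1 1752.4 and Fcgr1 7.07.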

How the results depend on the processing

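The fits without the libraries that went against their sex label, with Y-linked level as a covariate, without mitochondrial features and with thinned embryonic libraries, and the counts of lncRNA features overlapping no coding gene, were chosen only after the result was seen. Of the values of named genes under alternatives, 4457 of 4469 kept direction and side of the threshold in the E13.5 comparison, 1598 of 1919 in the age comparison and 2190 of 2392 in the TAC comparison; 8, 312 and 195 lost their call, 2, 9 and 7 gained one, and 2, 0 and 0 changed direction by edgeR or the other tools. With sham hearts as the reference, Hspb1 turned to -0.42998 and Acta1 to -0.76428. Libraries of unoperated adults were shallower than the rest. The cause was not tested unless the setting itself gives it, as with fewer or more features tested. Replicate numbers did not pair the libraries (r of the same number -0.133 to 0.123, -0.0632 to 0.152 and -0.0520 to 0.0218; 3 of 19, 5 of 12 and 0 of 8 libraries were closest to their own number), and a block for them gave 5534 and 4947, 151 and 137, and 2175 and 2012 features higher and lower.

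Counts higher and lower follow in this order. E13.5: without a filter 12197 higher, lncRNA 4847 and 1801; with the filter at 1 CPM lncRNA 1771 and 907; all 27 libraries in 1 fit lncRNA 2210 and 1369; 6-week reference lncRNA 1416 and 870; 16-week reference lncRNA 1556 higher; sham reference lncRNA 2345 and 1332; overlapping no coding gene 183 and 203. Age: DESeq2 lncRNA 9 higher; without a filter 219 and 289, lncRNA 10 and 68; filter at 1 CPM lncRNA 9 higher; all libraries in 1 fit 230 and 190, lncRNA 12 and 43; fold threshold 1 and 2, lncRNA 0 and 0 by edgeR (164 at unadjusted p under 0.05 without that threshold); without libraries against their sex label 74 and 64, lncRNA 13 lower; overlapping no coding gene 2 and 8. TAC: without a filter lncRNA 188 and 1659; fold threshold 462 and 499, lncRNA 30 and 353; overlapping no coding gene 57 and 205. With estimated correlation camera called 4 and 5 lists, 0 and 0 (2 at unadjusted p under 0.05) and 2 and 1. Neighbouring pairs in TAC gave a rho of 0.25241 at 1 to 20 kb, 0.15503 at 5 to 100 kb and 0.32034 when overlapping.

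With each library left out in turn, counts ran from 5457 to 5766 higher and 4941 to 5118 lower (lncRNA 595 to 759 and 510 to 557) in the E13.5 comparison, from 51 to 207 and 56 to 165 (2 to 8 and 9 to 29) in the age comparison, and from 2368 to 2840 and 2153 to 2729 (87 to 126 and 850 to 1067) in the TAC comparison. Named calls kept in every such fit numbered 126 of 126, 23 of 49 and 91 of 110.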

Other observations

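The comparison of sham with unoperated adult hearts was not planned before the files were seen. Markers of other cell types not described above also differed. At E13.5, smooth muscle markers went both ways (4 higher and 7 lower of 11, camera adjusted p = 0.921), with Cnn1 at 5.97 ± 0.14 and Rgs5 at -3.87 ± 0.23, and so did fibroblast markers (5 higher and 8 lower of 13; 0.0623), with Col1a1 at 2.01 ± 0.18 and Pi16 at -4.72 ± 0.12. Skeletal muscle markers had 4 higher and 1 lower of 5 (0.921), with Tnni2 at 4.66 ± 0.19 and Myh2 at -8.57 ± 0.19. Of 15 clock genes 12 fell (0.16), including Npas2 (-2.39 ± 0.19), and of 9 interferon response genes 6 fell (0.47), including Oas2 (-2.61 ± 0.21). Immediate early and heat shock genes had 6 higher and 3 lower of 15 (0.47), with Atf3 at 1.79 ± 0.19 and Dusp1 at -2.10 ± 0.26. Against sham hearts, 14 of 15 interferon response genes fell (median -1.91, against -0.46 here), immediate early and heat shock genes had 7 higher and 7 lower of 18 (median -0.13, against 0.40 here) and 7 of 7 skeletal muscle markers rose. No skeletal muscle marker was called lower with that reference, so the fall of Myh2 was called only against unoperated adults. Nerve markers had 1 higher and 1 lower of 4 (0.921), and their median (-0.78) and mean (0.15) differed in sign. Adipocyte markers had 1 higher and 1 lower of 2, the lymphocyte marker Igh-6 fell (-2.46 ± 0.19) and the lung marker Ager rose (3.52 ± 0.35), all without a camera test. No liver marker and no known lncRNA was tested in this comparison. Against sham hearts, 5 liver markers were tested, of which 3 were higher and 1 lower at E13.5 (median 6.81).

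In TAC hearts, 6 of 15 interferon response genes rose (0.103), including Irf7 (0.85 ± 0.20). Atrial markers had 3 higher and 2 lower of 9 (0.0411, and adjusted p = 0.2 with an estimated correlation), with Dkk3 at 2.37 ± 0.35 and Kcnj3 at -1.13 ± 0.12. Cardiac transcription factors had 6 higher and 6 lower of 19 (0.395), with Nkx2-5 at 0.53 ± 0.13 and Tbx5 at -0.93 ± 0.08. Renin-angiotensin and natriuretic genes had 3 higher and 3 lower of 15 (0.716; median 0.07, mean -0.04), with Ednrb at 0.48 ± 0.12 and Corin at -0.79 ± 0.08. Cell cycle genes had 5 higher and 1 lower of 30, or 3 and 1 adjusted over the list alone (0.118), with Mcm2 at 0.76 ± 0.14. Endothelial markers had 2 higher and 2 lower of 13 (0.45), with Cldn5 at 1.16 ± 0.16. Smooth muscle markers had 4 higher and 1 lower of 11 (0.162), with Des at 0.88 ± 0.07. Without the libraries that went against their sex label, which left 2 hearts per group, smooth muscle markers turned to 1 higher and 4 lower. Imprinted growth genes had 1 higher and 1 lower of 11 (0.741), oncofetal genes 1 higher of 10 (0.728), epicardial markers 2 higher of 4 (0.237), lymphocyte markers 1 higher of 4 (0.37) and adipocyte markers 1 higher and 1 lower of 3 (0.716), with Car3 at -2.89 ± 0.50. None of 6 erythroid markers passed by edgeR (0.354), and neither did the liver marker Ahsg (0.66 ± 0.32). In the edgeR fit without the libraries that went against their sex label, 4 of the 6 erythroid markers were called higher. There Hbb-b2 stood at 0.68 (adjusted p = 0.00176), Hba-a1 at 0.53 (2.94e-04) and Ahsg at 0.74 (0.018). Skeletal muscle markers had 1 higher of 2, or 1 higher and 1 lower adjusted over the list alone, with Tnnt3 at 1.70 ± 0.36. In the 8 fits that each left out 1 library, the epicardial markers Wt1 and Tcf21 each lost their call in 5, and the number higher ran from 0 to 2. The same count ran from 2 to 7 for interferon response genes, of which Isg15 and Oas1a each lost their call in 6, and from 2 to 7 for cell cycle genes, with Cdca8 lost in 6 and Cdc20 in 1. For smooth muscle markers it ran from 2 to 4, with Cnn1 and Cspg4 each lost in 5. Flt1, Ace, Eno3 and Sucla2 lost their calls in 4, 1, 6 and 3.

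Between 6 and 16 weeks, erythroid markers had 1 of 5 higher, or 3 adjusted over the list alone (3.50e-05, and adjusted p = 0.373 with an estimated correlation). Immediate early genes shifted up as a list (12 tested; 0.00353, and adjusted p = 0.452 with an estimated correlation) without a called member. Dusp1, on this list, stood at 328.52 CPM in 16-week replicate 6 against 80.44 to 119.3 in the other 16-week hearts. Whether the list shift rests on that library was not tested. The fetal gene programme had 1 higher and 1 lower of 10, or 3 and 3 adjusted over the list alone (0.916; median 0.21, mean -0.20), contractile genes 1 higher and 2 lower of 23, or 2 and 3 (0.948; 0.08 and -0.04), oncofetal genes 1 lower of 7 (0.29), Dnmt3a (-0.40 ± 0.07), smooth muscle markers 1 higher of 10, or 1 and 1 (0.0697) and nerve markers 1 lower of 3 (0.645). In the 12 fits that each left out 1 library, Tnnt2 of the fetal gene programme, Hspb1 of the Z disc list and Des of the Z disc list and smooth muscle markers lost their calls in 5, 3 and 10. No member was called among 18 glycolysis (0.948), 8 cell cycle (0.358), 18 potassium channel (0.665), 15 clock (0.907), 9 interferon (0.907), 15 renin-angiotensin (0.916), 13 endothelial (0.916), 7 atrial (0.645) and 3 epicardial genes (0.925), though 1 potassium channel and 1 atrial gene were lower when adjusted over the list alone. Sham hearts differed from unoperated adults in 1695 features higher and 1863 lower of 11171, with encoding, age and surgery going together.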
